A study of Mus musculus with 2 samples.

How the data were processed

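H3K27ac, acetylation of lysine 27 of histone 3, marks active promoters and enhancers. It was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the facial prominences of mouse embryos, the swellings from which the face grows, at 10.5 days of development. The tissue came from strain B6NCrl and pooled male and female embryos, per the labels. There was 1 group of 2 biological replicates. Replicate 1 was a pool of 69 embryos and replicate 2 a pool of 51, so each value stands for many animals and the spread between replicates is that between pools. The group and replicate numbers were taken from the labels.

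Of the processing before deposition, the labels and the deposited notes give the build (mm10) and the origin of each file. The peak caller, its version and its threshold, and the aligner, are not given in the sources used here. The authors deposited 4 peak lists. The list of replicate 1 was derived from that library's filtered alignment and 2 further files, and the list of replicate 2 from its own alignment and 1 further file, and the deposited notes do not describe these further files. The pooled list was made from both alignments, and the list of replicated peaks from the pooled list and both replicate lists, by a rule that the notes do not state.

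Each deposited peak carries a fold enrichment, a ratio to background that has no unit. The name of that column rests on the file format and on values that all lie above 1, since no source used here states how it was made. The deposited lists also give each peak's −log10 p and −log10 q, with p and q from the authors' peak caller. A display score for each peak, deposited as a whole number, was not used. Fold enrichments are the authors' own values per peak and were used only to describe, rank or filter peaks within a list. The number of sequenced reads behind each list is unknown here, so no interval that needs read depth is given. The 95% intervals of shares are Wilson intervals, cover counting error over peaks, genes or windows only, and treat these as independent, which neighbouring peaks are not.

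Chromosome names and lengths of the lists were checked against the GRCm38 reference genome, the build called mm10, and its GENCODE release M21 annotation. Analyses used 21 chromosomes (the autosomes, X and Y). Peaks on contigs without a chromosome position were left out of all analyses but the totals per list and the comparison of the pooled and replicated lists. A TSS is the start of an annotated protein-coding transcript of a protein-coding gene, and there were 54327 of them in 21829 genes. A promoter peak lay within 1 kb of a TSS, and a gene with such a peak is called marked. A distal peak lay more than 2.5 kb from every TSS and was assigned to the gene of the TSS nearest to its midpoint within 100 kb. That assignment is by position only. Positions are given 1-based on mm10.

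Replicates were compared by the share of peaks overlapped by at least 1 bp, beside 100 random placements of the other replicate's peaks on their own chromosomes. Classes of position were set beside 100 random placements of the replicated peaks. Of 18 gene lists, 16 were written out by hand and the olfactory receptor and cytosolic ribosomal protein genes were taken by symbol. All but 1 symbol of the lists matched the annotation, and that gene entered under its older symbol T. Promoter marking was tested per list with a two-sided Fisher's exact test against all other protein-coding genes. Distal peaks per gene were tested with a two-sided permutation test against 10000 random lists matched on the size of each gene's domain, which is the sequence nearest to its TSSs, in 10 classes. Distal peaks were also joined into stitched domains where they lay 12.5 kb or less apart. These domains were ranked by the sum over peaks of width times fold enrichment. Each was named for the gene of the nearest TSS whose peaks held the largest part of that sum.

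For DNA words, a window of 400 bp at the midpoint of each distal peak was compared with 1 control window from the same chromosome. Control windows lay outside pooled peaks and more than 2.5 kb from a TSS. They were matched on GC content in bins of 1% and on the share of repeat-masked bases in bins of 10%. Of 60169 distal peaks, 59748 were matched. A further 419 had no control left, and windows that held an unsequenced base were left out. A two-sided Fisher's exact test was made for each of 26 words, and the mirror image of each word, read backwards and not complemented, served as a baseline of the same base composition. Pairs of E-box and homeodomain words were tested in 4 layouts at spacers of 0 to 20 bp, each against the control windows and not against other spacers. Replicate-only peaks were those among the 30000 peaks of lowest p of a replicate that no peak of the other replicate overlapped, and their nearest genes were tested per list with a two-sided Fisher's exact test. P-values were adjusted by the Benjamini-Hochberg method within each family (lists, words, spacers or replicate-only tests), and a test passed at an adjusted p under 0.05. Genes, peaks and windows are not independent replicates, so these tests describe the peak lists of these pools.

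Gene lists, words, tests and most alternatives were chosen before the data were examined. So was the rule for named genes. It takes the nearest genes of the 20 top stitched domains and of the 10 distal peaks of highest fold enrichment, and from each list the 4 members with the most distal peaks. It also takes the unmarked members of the 4 facial lists and the marked members of lists of other tissues, where these were 5 or fewer. Other genes are named as chosen after their values were seen.

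Alternatives left out either replicate, by taking the same number of best-ranked peaks of the other one, or kept peaks with a −log10 q of at least 5. Others changed the overlap, the peak list, the promoter window, the distance limit, the joining distance, the window size or the controls. An alternative that keeps the replicated peaks overlapped in both replicate lists was added after seeing the data. The computations were tested on simulated data before use. Planted overlap of 50% was found at 50%. Lists of 30 genes with 3 times the distal peaks had a p under 0.05 in 100% of 40 draws, and unchanged lists in 3% of 100. For promoter marking, lists with 28 of 30 genes marked were found in 100% of 40 draws, and random lists in 3% of 100. Planting TAATTA in 2% of windows raised its share by 1.75 points, since some of these windows held the word already, and 0 of 25 other words passed. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.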

Results

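H3K27ac peaks were collected from the facial prominences of mouse embryos at 10.5 days, in 2 biological replicates of 69 and 51 pooled embryos. The list of replicate 1 held 131727 peaks over 66.4 Mb, with a median width of 277 bp and a median fold enrichment of 2.87. The list of replicate 2 held 146748 peaks over 75.2 Mb, with a median width of 287 bp and a median fold enrichment of 3.14. The pooled list held 176643 peaks over 103.5 Mb, and the list of replicated peaks 79793 over 77.5 Mb, which is 2.84% of the genome. Replicated peaks had a median width of 651 bp and a median fold enrichment of 3.23, and the highest reached 47.2. The sequencing depth of the libraries is unknown here. With 1 group, the only comparison between samples was that of the replicates, and the other comparisons set gene lists, regions or DNA words against a background within the replicated peaks.

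The first question was whether the pools of embryos gave the same peaks. Strong promoters had peaks in both lists, with fold enrichments given on each list's own scale. The promoter of Actb, which encodes cytoplasmic actin, had a fold enrichment of 39.7 in replicate 1 and 46.6 in replicate 2. Nr2f1, a nuclear receptor gene of the facial mesenchyme list (chromosome 13, 78188973 to 78199757), had 33.4 and 37.6. Alx4, a homeobox gene of the frontonasal mesenchyme (chromosome 2, 93642384 to 93681339), had 26.5 and 24.4, and Barx1, a homeobox gene of the jaw mesenchyme, had 10.1 and 10.6. Nr2f1 and Actb were chosen for this comparison after their values were seen. Edn1, Wnt9b, Shh and Grhl3, the genes of the facial lists without a replicated promoter peak, had one of fold enrichment 4.04, 4.28, 2.99 and 2.47 in replicate 2 and none in replicate 1.

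Over all peaks, 63.4% of those of replicate 1 were overlapped by replicate 2 (95% interval 63.2 to 63.7%), against a mean of 6.08% over 100 random placements. Of those of replicate 2, 54.9% were overlapped by replicate 1 (54.6 to 55.1%), against 5.49% in random placements. The lists shared 47.2 Mb of the 94.4 Mb that either covered. Overlap depended on rank. All of the 10000 peaks of lowest p in each replicate were overlapped by the other. For ranks 20001 to 30000 the shares were 94.5% and 92.9%, for ranks 30001 to 50000 they were 77.2% and 73.4%, and in the last bins 37.7% and 27.8%. Across the 83556 overlapped peaks of replicate 1, fold enrichments of the replicates had a Spearman correlation of 0.637 and a Pearson correlation of 0.825 on the log2 scale. That is across peaks, which are not independent replicates.

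**Figure D1:**
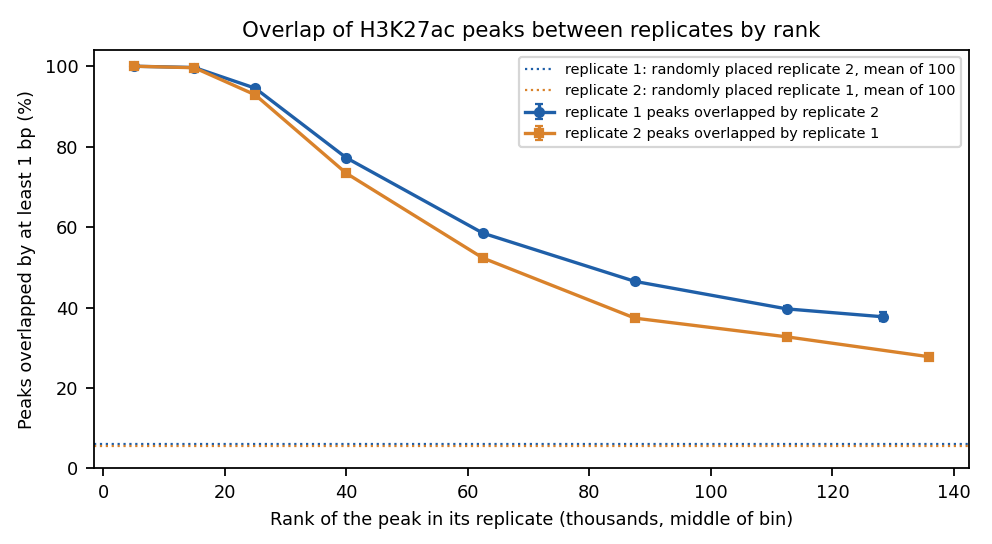
Share of peaks (%) of each replicate overlapped by at least 1 bp by a peak of the other, against the rank of the peak by the authors' p, divided by 1000, at the middle of each bin, with 95% Wilson intervals that are mostly smaller than the points. Dotted lines give the mean over 100 random placements (6.08% for replicate 1, 5.49% for replicate 2), and the observed shares fall from 100% to 37.7% and 27.8%.

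The replicated peaks were a subset of the pooled list. All 79793 had an identical entry there, 45.2% of its peaks with 74.9% of its bases. Of them, 68276 (85.6%) were overlapped by a peak in both replicate lists, 5435 in replicate 1 alone, 5639 in replicate 2 alone and 443 in neither. The 11517 peaks not overlapped in both had a median fold enrichment of 2.66, against 3.41 for those overlapped in both. All 67929 pooled peaks that shared at least 50% of either peak with both replicates were in the replicated list. Pooled peaks left out were narrower, at a median of 238 bp, and had a median fold enrichment of 2.26.

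Replicated peaks were concentrated at promoters, although most lay far from any. Of 79786 peaks on chromosomes, 16469 (20.6%) lay within 1 kb of a TSS, which was 5.45 times the random share of 3.79%. Other exons held 3.69%, against 2.44% at random, and introns 38.2%, against 36.6%. Sequence between genes held 37.5%, against 57.2% at random. Peaks more than 2.5 kb from any TSS numbered 60169, or 75.4%, against 92.9% at random. Promoter peaks had a median width of 1396 bp and a median fold enrichment of 9.39, and distal peaks 568 bp and 3.04. A lncRNA TSS lay within 1 kb of 2378 distal peaks (3.95%), since only protein-coding transcripts defined promoters. In all, 14195 of 21829 protein-coding genes (65.0%) had a marked promoter, 13931 of them also in both replicate lists, and 8625 genes (39.5%) had at least 1 distal peak assigned.

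The next comparison asked which groups of genes had H3K27ac at their promoters. All 38 transcription factor genes of the facial mesenchyme were marked (100%, interval 90.8 to 100%), against 65.0% of other genes (Fisher's exact test, adjusted p = 5.1e-07). Among them were Sox9, needed for cartilage (chromosome 11, 112782224 to 112787760), with a fold enrichment of 19.1, Alx4 with 27.6, Twist2 with 19.4 and Barx1 with 11.7. The marked share was also higher for clefting genes, craniofacial signalling genes and the Dlx, Hand and endothelin genes of the mandibular arch. It was lower for Hox genes of paralogue groups 5 to 13, which pattern the trunk and limbs, for pluripotency, olfactory receptor and hepatic genes. Over the 18 lists, 9 were marked more often than other genes, 4 less often, and 5 did not pass.

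Of the 14 mandibular arch genes, 13 were marked (92.9%; Fisher's exact test, adjusted p = 0.037), with fold enrichments of 11.5 at Ece1, which encodes the enzyme that activates endothelins, 6.21 at Dlx4 and 14.6 at Gsc. The unmarked member was Edn1, the gene of endothelin 1. With each gene's own 5′ end as the only TSS, 85.7% were marked and the test did not pass (adjusted p = 0.14, Fisher's exact test). Craniofacial signalling genes were marked in 27 of 30 (90.0%; Fisher's exact test, adjusted p = 0.0067), with 3.79 at Wnt11, 6.73 at Bmp7, 27.7 at Fgfr2 and 18.2 at Tgfbr2. The peak counted for Fgfr2 also covered the TSS of Ctbp2, at the far end of the annotation of Fgfr2, so its value is not that of Fgfr2 alone. Shh, Edn1 and Wnt9b had no replicated peak there. Clefting genes, in which variants are linked to cleft lip or palate, were marked in 26 of 28 (92.9%; Fisher's exact test, adjusted p = 0.0029), among them Nectin1 with 26.8, the Hedgehog receptor gene Ptch1 with 30.5, Pax7 with 7.4 and Fgfr1 with 23.5. The unmarked members were Grhl3 and Wnt9b. From the best-ranked peaks of replicate 1 alone, 78.6% of the clefting genes were marked and the test did not pass (Fisher's exact test, adjusted p = 0.13).

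Promoters of other cell types that the dissected tissue can hold were marked too. Surface ectoderm genes were marked in 18 of 20 (90.0%; Fisher's exact test, adjusted p = 0.027), with 15.8 at Grhl2, 7.78 at Epcam and 7.4 at Tfap2c, and Grhl3 and Krt14 unmarked. Neural and placodal genes were marked in 21 of 22 (95.5%; Fisher's exact test, adjusted p = 0.0030), with 17.2 at Sox2 and 10.4 at Sox1, and Phox2b unmarked. A promoter peak at 2 of these 21 also covered the TSS of another gene. Endothelial genes were marked in 15 of 16 (93.8%; Fisher's exact test, adjusted p = 0.026), with 24.3 at Fli1, 7.91 at Eng, 3.51 at Cdh5 and 3.60 at Erg, and Tek unmarked. By Fisher's exact test the endothelial call did not hold from the best-ranked peaks of replicate 2 alone (75.0%, adjusted p = 0.50) or of replicate 1 alone (81.3%, 0.25), and the ectoderm call did not hold from those of replicate 1 alone (80.0%, 0.23). Both also missed the threshold of Fisher's exact test with peaks of a −log10 q of at least 5 (87.5% and 85.0%, both 0.091) and with each gene's own 5′ end (adjusted p = 0.36 for endothelial and 0.061 for ectoderm genes), and the endothelial one with peaks overlapped in both replicate lists (87.5%, 0.091). Krt14, Phox2b and Tek were named after their values were seen.

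Most lists of other tissues did not pass the test. Of the erythroid and haematopoietic genes 8 of 15 were marked (53.3%; Fisher's exact test, adjusted p = 0.47), with 7.71 at Runx1 and 4.32 at Spi1. Skeletal muscle genes were marked in 7 of 14 (50%; Fisher's exact test, adjusted p = 0.34), with 6.11 at Tbx1, a gene of the head muscle progenitors, and 5.41 at Des. Cardiac genes were marked in 8 of 15 (53.3%; Fisher's exact test, adjusted p = 0.47), with 5.81 at Hcn4. Limb and trunk patterning genes were marked in 9 of 15 (60%; Fisher's exact test, adjusted p = 0.79), with 12.2 at Pitx1, which is also expressed in the mandible, 5.03 at Meox1 and 3.96 at Tbx4. Hepatic genes were marked less often, in 5 of 16 (31.3%, interval 14.2 to 55.6%; Fisher's exact test, adjusted p = 0.013). These were Foxa3 with 16.2, Apoa1 with 8.36, Trf with 8.03, Foxa2 with 2.94 and Ahsg with 2.47, and the peaks at Foxa3 and Trf also covered the TSS of another gene. At Apoa1 the promoter value was 2.25 in replicate 1, and replicate 2 had no promoter peak. Peaks that end just outside 1 kb of a TSS are not counted, so these values may not describe the same peak. Fisher's exact test did not pass for hepatic genes from the best-ranked peaks of replicate 2 alone (43.8%, adjusted p = 0.16) or with all pooled peaks (50%, 0.15). Of 12 pluripotency genes Klf2 alone was marked, with 5.98 (8.33%; Fisher's exact test, adjusted p = 0.00028).

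Hox genes were listed by paralogue group, with groups of higher number expressed further back in the embryo. None of the 27 genes of groups 5 to 13 had a replicated promoter peak (0%, interval up to 12%; Fisher's exact test, adjusted p = 4.2e-12). In the pooled list Hoxd13 alone had one, with a fold enrichment of 2.34, and in the list of replicate 2 Hoxa11 (2.67), Hoxa7 (2.59) and Hoxd8 (2.47) had one, genes named after their values were seen. In the list of replicate 1 none did. Of the 12 genes of groups 1 to 4, which are expressed in the hindbrain and the posterior pharyngeal arches, 7 were marked (58.3%; Fisher's exact test, adjusted p = 0.79). The broadest of these peaks was at Hoxa2, which patterns the second pharyngeal arch (chromosome 6, 52162417 to 52164831), with 4865 bp and a fold enrichment of 8.02, and Hoxb3 and Hoxd3 had 3.51 each and Hoxb1 2.62. The difference between the Hox lists was not itself tested. All 18 housekeeping genes were marked (Fisher's exact test, adjusted p = 0.0021), with 46.3 at Actb, 40.8 at Ywhaz, 30.4 at Gapdh and 23.9 at Eef1a1. Ribosomal protein genes were marked in 76 of 79 (96.2%; Fisher's exact test, adjusted p = 2.3e-10). A promoter peak at 19 of these 76 and at 3 of the 18 housekeeping genes also covered the TSS of another gene. The unmarked Rpl39l, Rpl10l and Rpl3l, named after their values were seen, are the tissue-restricted paralogues. Of 1133 olfactory receptor genes 6 were marked (0.530%, interval 0.243 to 1.15%), against 68.6% of other genes, and Fisher's exact test passed for this list.

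**Figure D2:**
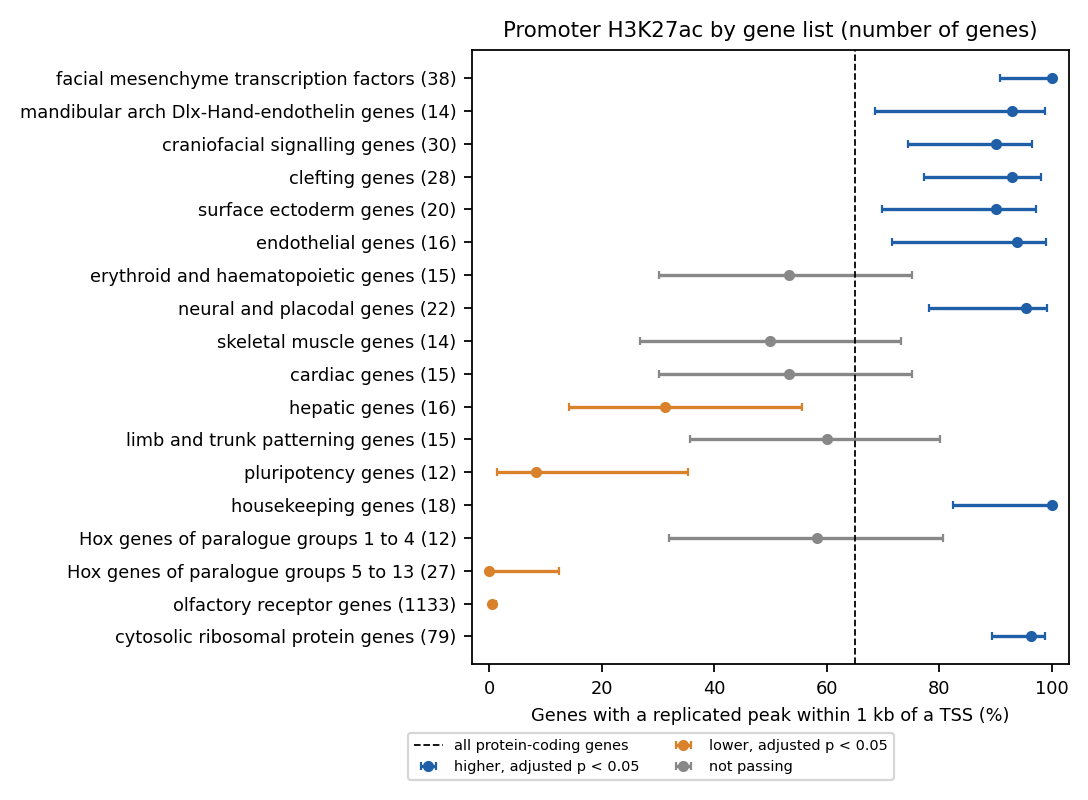
Share of genes (%) with a replicated peak within 1 kb of a TSS in 18 lists, with 95% Wilson intervals and the number of genes in parentheses; the dashed line marks the 65.0% of all protein-coding genes. Colours give the adjusted p of Fisher's exact test, with the facial mesenchyme list at 100% and Hox genes of paralogue groups 5 to 13 at 0%.

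Distal peaks, where enhancers are sought, were then counted around the genes of each list. Facial mesenchyme transcription factor genes had a mean of 10.6 distal peaks each, 2.49 times the 4.24 of random lists with domains of the same size (permutation test, adjusted p = 0.0024), and 36 of 38 had at least 1. The highest numbers were 31 around Sox9, 28 around Barx1, 24 around Alx4 and 23 around Twist2, where the strongest distal peaks had fold enrichments of 9.01, 10.1, 7.20 and 8.22. Mandibular arch genes had 13.1 against 3.39 (3.88 times; permutation test, adjusted p = 0.0018), with 32 at Ece1, 21 at Dlx4 and 18 at Gsc. Craniofacial signalling genes had 10.4 against 4.46 (2.34 times; permutation test, adjusted p = 0.0090), with 41 at Wnt11, 34 at Bmp7, 28 at Fgfr2 and 24 at Tgfbr2. The count of Fgfr2 can include peaks around Ctbp2, since an annotated TSS of Fgfr2 lies beside that gene. Clefting genes had 8.54 against 3.77 (2.26 times; permutation test, adjusted p = 0.015), with 39 at Nectin1, 20 at Ptch1, 17 at Pax7 and 16 at Fgfr1. The 4 facial lists share members and hold 94 genes in all, of which 90 were marked and 89 had a distal peak, 979 peaks together. Random lists were not matched on promoter marking, and 90.0 to 100% of each facial list was marked, against 65.0% of all genes. An excess that goes with a marked promoter in general was therefore not set apart.

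Within 200 kb centred on the start of Barx1 (chromosome 13, 48562998 to 48762997) there were 35 replicated peaks, from 52 in replicate 1 and 66 in replicate 2. The promoter peak of Barx1 was 3821 bp wide, and most others lay between the gene and the right edge of the region. Ptpdc1 was the other protein-coding gene there.

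**Figure D3:**
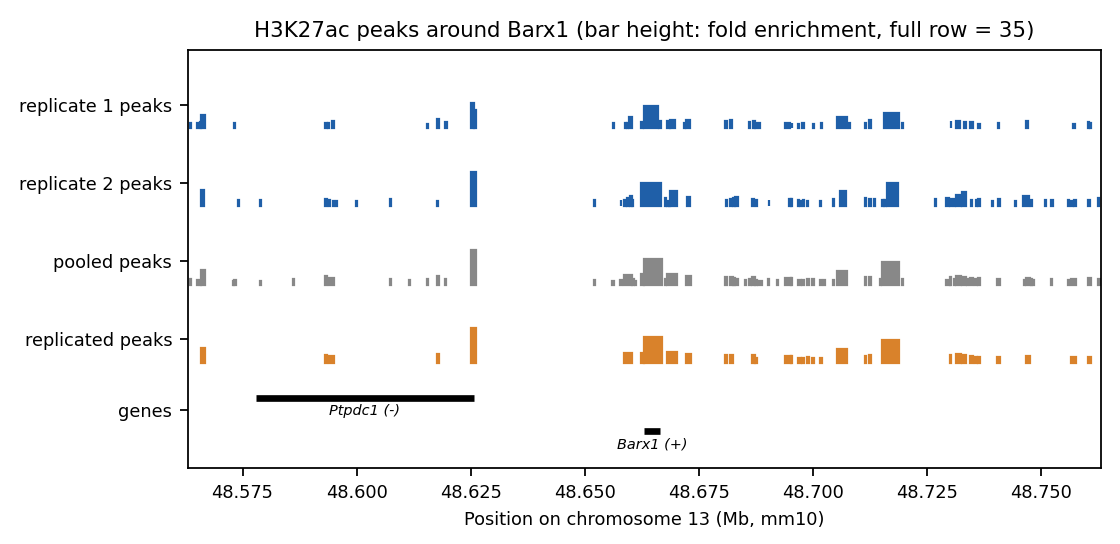
Peaks of the 4 lists along 200 kb of chromosome 13 around Barx1, to scale in Mb on mm10, with bar height proportional to the authors' fold enrichment within each list and genes below with their strand. The region holds 52 peaks of replicate 1, 66 of replicate 2, 72 pooled and 35 replicated peaks.

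In the permutation test the mandibular arch and clefting calls did not hold when distal peaks were assigned up to 500 kb away (adjusted p = 0.056 and 0.096), nor did the clefting one for the summed width of distal peaks (0.055). Endothelial, surface ectoderm and neural lists did not pass. Endothelial genes had 7.19 distal peaks against 3.15 (2.28 times; permutation test, adjusted p = 0.13), with 25 at Fli1, 17 at Eng and 16 each at Cdh5 and Erg. Surface ectoderm genes had 5.20 against 2.44 (2.13 times; permutation test, adjusted p = 0.14), with 20 at Tfap2c, 15 at Grhl2, 14 at Grhl3 and 10 at Epcam. The strongest distal peaks at Grhl2 and Epcam reached fold enrichments of 24.1 and 23.7. The endothelial and ectoderm ratios were close to those of clefting (2.26) and craniofacial signalling genes (2.34), in lists of fewer genes (16 and 20 against 28 and 30). Ratios of that size were thus not particular to the facial lists, although the endothelial and ectoderm lists did not pass. The ectoderm list also shares members, such as Irf6 and Grhl3, with the clefting list. Whether an excess is particular to the facial lists was therefore not settled. Neural and placodal genes had 3.68 against 3.72 (permutation test, adjusted p = 0.92), with 21 at Sox2, 12 at Sox1, 7 at Neurog1 and 6 at Pax6.

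Among the remaining lists the values were 2.40 distal peaks per gene against 1.71 for erythroid and haematopoietic genes, with 31 at Runx1, 3 at Ptprc and 2 at Spi1, and 2.71 against 2.53 for skeletal muscle genes, with 11 at Tbx1, 9 at Chrna1, 8 at Des and 4 at Myog. Cardiac genes had 1.53 against 2.74, with 5 at Hcn4, 4 at Tnnt2 and 3 each at Tnni1 and Myl7, and hepatic genes 0.875 against 1.85, with 6 at Apob, 2 each at Ahsg and Foxa2 and 1 at Trf. Limb and trunk patterning genes had 4.40 against 3.37, with 22 at Meox1, 15 at Tbx4, 11 at Uncx and 10 at Pitx1, and pluripotency genes 1.17 against 2.36, with 8 at Esrrb, 2 each at Nanog and Utf1 and 1 at Pou5f1. Housekeeping genes had 2.00 against 1.28, with 11 at Ywhaz, 7 at Eef1a1, 5 at Actb and 3 at Gapdh. Ribosomal protein genes had 1.61 against 1.09, with 14 at Rplp1, 12 at Rps24 and 11 each at Rpl29 and Rpl37a, and Hox genes of groups 1 to 4 had 0.583 against 0.843, with 2 each at Hoxb3 and Hoxd3 and 1 each at Hoxa2 and Hoxb1. Adjusted p-values of these 9 lists lay between 0.30 and 0.92.

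Fewer distal peaks than in random lists were found for Hox genes of groups 5 to 13, with 0 against 0.433 (permutation test, adjusted p = 0.028), and for olfactory receptor genes, with 0.0335 against 0.745 (0.0018). The olfactory receptor genes with the most were Olfr267 with 10, Olfr1423 and Olfr412 with 4 each and Olfr875 with 2. In the permutation test the Hox call did not hold with peaks of a −log10 q of at least 5 (adjusted p = 0.11) or with peaks overlapped in both replicate lists (0.056). The unadjusted p of the mandibular arch and olfactory receptor lists, 0.00020, is the smallest that 10000 random lists can give. In total 4 lists had more distal peaks, 2 fewer, and 12 did not pass.

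**Figure D4:**
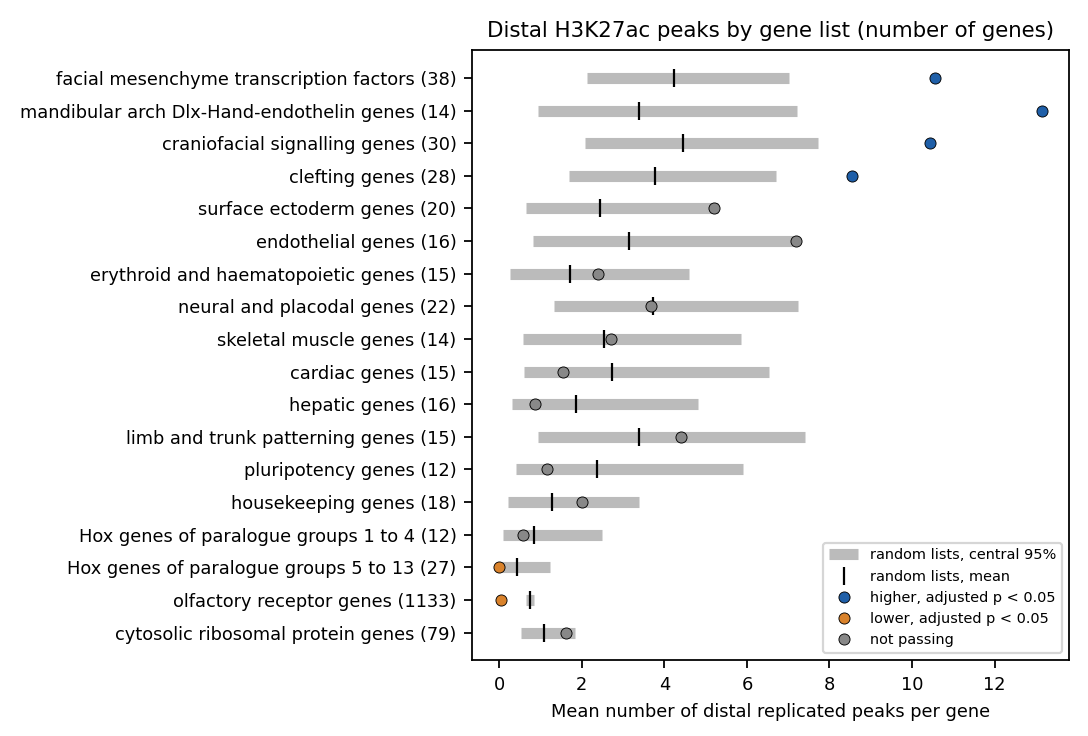
Mean number of distal replicated peaks per gene in 18 lists (points), with the mean (tick) and the central 95% (grey bar) of 10000 random lists matched on domain size. The 4 facial lists lie between 8.54 and 13.1, above their grey bars. Endothelial genes at 7.19 also lie just above theirs, which ends at 7.125, but did not pass after adjustment.

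The regions with the most distal H3K27ac were nearest to genes outside the facial lists. Joining distal peaks gave 19283 domains, of which the top 20 held 6.97% of the summed width times fold enrichment and the top 100 held 16.5%. The gene nearest to the peaks with the largest part of a domain's sum was a facial-list gene in 0 of the top 20 and in 3 of the top 100, at Snai1 (rank 34), Bmp7 (77) and Ece1 (91). Over all domains the share was 2.07%. The first domain (chromosome 2, 30584813 to 30798147) had 72 peaks and held 0.865% of the sum, with 1700001O22Rik and Cstad as its nearest genes. The next was nearest to Npvf and Nfe2l3 (chromosome 6, 50878744 to 51175141), with 119 peaks and 0.538%. Peaks of the others among the top 20 were nearest to the transcription factor genes Foxl1, Foxp4 and Tfeb, to Igf2 and Igfbp4, which encode an insulin-like growth factor and a binding protein of these factors, to the kinase and phosphatase genes Src and Dusp7, and to Zfp36l1, Zfp36l2, Rad51b, Sulf2, Prex1, Gse1, Gins2, Haao, Mrpl23, Tnnt3, 4930558K02Rik, Dnm3, Gm26897, Mn1, Tex44, Ptma, Nmur1, Fignl1, Ddc, Sorl1, 1700018B08Rik, 1700122O11Rik, 1700067P10Rik, Mdfi, Acot11, Ssbp3, Ccr7, Tns4, Slc38a10, Bahcc1, Ppif, Zmiz1, Nnat, Blcap, Poc1a and Rpl29. Of the top 20, 2 lay within 100 kb of a facial-list TSS, the first at 36.8 kb from Prrx2 and that of Foxl1 (chromosome 8, 121149515 to 121403424) at 33.3 kb from Foxc2. Within 500 kb there were 4, with Gse1's domain near Crispld2 and Haao's near Thada added. These shares exceeded those of the 19263 other domains, 1.77% within 100 kb (Fisher's exact test, unadjusted p = 0.048) and 6.58% within 500 kb (p = 0.039). The comparison was chosen after the result was seen and took no account of domain length. A longer domain lies near any given gene more often, so it leaves open whether strong domains lie nearer to facial-list genes.

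Single distal peaks of highest fold enrichment lay 32.7 kb from A830005F24Rik (chromosome 13, 48545160 to 48547401, 46.4), at 16.0 and 75.3 kb from the chromatin remodeller gene Chd2 (42.4 and 39.9) and 90.1 kb from Ppm1h (40.9). They were followed by peaks near Tex44 (38.1), Sirt4 (37.8), Rps6ka1 (35.6), A930004D18Rik (35.3, in an intron), Zmiz1 (35.1) and Slc38a10 (34.9). All of these but the one in A930004D18Rik lay between protein-coding genes, and 6 of the 10 covered an annotated lncRNA TSS.

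DNA words of transcription factor families were then counted in windows of distal peaks. The homeodomain core TAATTA, recognised by the ALX, DLX, MSX and LHX families, was in 6.17% of peak windows and 4.44% of matched control windows, a ratio of 1.39 (95% interval 1.32 to 1.46; Fisher's exact test, adjusted p = 1.3e-39), while its mirror image had a ratio of 1.13. The forkhead word GTAAACA was in 5.15% against 3.72% (1.38, 1.31 to 1.46; Fisher's exact test, adjusted p = 3.3e-32). Higher ratios were found for the rarer words of RFX (1.67) and MEF2 (1.62) and for TCAGGTTTC, the word of Six1 and its paralogues (1.43), although the mirror image of the RFX word had 1.5. The words of POU (1.26), ETS (1.17), TEAD (1.16), TFAP2 (1.16), RUNX (1.12), EBF (1.10), SOX (1.10) and TCF and LEF (1.06) were also more frequent, and so was the E-box CAGCTG of myogenic and proneural factors (1.14, 30% against 26.4%). The mirror image of the TCF and LEF word was as frequent, with a ratio of 1.06.

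Less frequent than in controls were the words of REST, a repressor of neuronal genes (0.821), of MEIS and PKNOX (0.954) and the nuclear receptor word AGGTCA (0.974). The mirror images of the MEIS word (0.948) and of AGGTCA (0.962) were at least as depleted, while that of the REST word had 0.987. For AGGTCA the difference was thus no more than that of its baseline. The MEIS word TGACAG and its mirror image GACAGT share the run GACAG, so that baseline cannot decide for the MEIS word. The E-box CAGATG, the form bound by TWIST1, was in 32.6% of peak windows and 32.4% of control windows (ratio 1.00, interval 0.988 to 1.02; Fisher's exact test, adjusted p = 0.65), while its mirror image had a ratio of 0.854. It passed as slightly more frequent in windows of 1000 bp (1.01; Fisher's exact test, adjusted p = 0.044). The bicoid-type homeodomain word of PITX, GSC and OTX (1.02), the words of GATA (1.04), AP-1 (1.03), GLI (1.02), NFI (1.09), CREB (0.882) and HNF4 (0.886), and the insulator word of CTCF (0.977) did not pass either. Of 26 words 14 were more frequent, 3 less and 9 did not pass. These ratios depended on the choice of controls, and which property of the controls mattered was not tested. Against windows 5 kb beside each peak, which had a GC content of 44.7% against 51.6% in the peaks, the ratio was below 1 for TAATTA (0.586), the MEF2 (0.733), POU (0.661), RUNX (0.908) and TCF and LEF words (0.850) and GTAAACA (0.999), and above 1 for AGGTCA (1.07) and the MEIS (1.12) and REST words (1.24). Words that gained a call there as more frequent were those of CTCF (1.61), GLI (1.71) and AP-1 (1.06) and CAGATG (1.1), and the SOX word lost its call (1.00). In windows of 1000 bp the CTCF (1.57) and CREB (1.16) words passed as more frequent and the HNF4 word as less frequent (0.904). From the best-ranked peaks of replicate 2 alone the Six1 word did not pass (1.15; Fisher's exact test, adjusted p = 0.093) and the GATA word was less frequent (0.940, 0.043). From those of replicate 1 alone the RFX word did not pass (1.24; Fisher's exact test, adjusted p = 0.074) and the NFI word, found in 24 peak and 22 control windows of the main comparison, did (2.0, 0.046). The ETS word did not pass in peaks overlapped in both replicate lists (Fisher's exact test, adjusted p = 0.053), nor the POU word at the authors' summits (0.082).

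**Figure D5:**
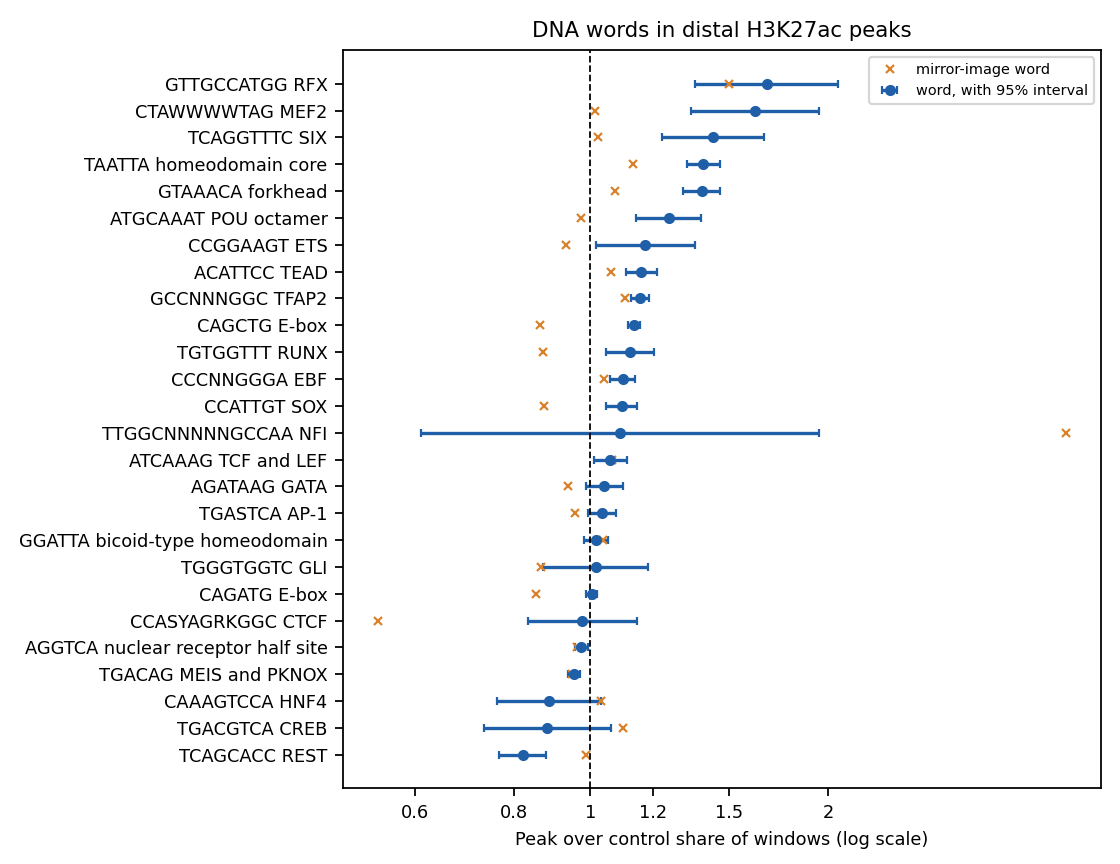
Ratio, on a log axis, of the share of distal peak windows to the share of matched control windows that hold each of 26 DNA words (circles, 95% intervals) or its mirror image (crosses). TAATTA lies at 1.39 with its mirror image at 1.13, and CAGATG at 1.00.

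Composite sites of CAGATG and a homeodomain core are known from cranial neural crest cells, so layouts and spacers of these words were tested. Each was compared with control windows and not with other spacers. The homeodomain core TAATTA was itself more frequent in peaks (ratio 1.39), so a layout can pass without a preferred spacing. Of 84 layouts and spacers 0 passed by Fisher's exact test after adjustment, and 7 had an unadjusted p under 0.05, 6 of them with more sites in peaks. The smallest were AATTA followed by CAGATG after 4 bp, in 27 peak and 8 control windows (Fisher's exact test, p = 0.0019, adjusted p = 0.12), and TAATT followed by CAGATG after 5 bp, in 26 and 8 windows (p = 0.0029, adjusted p = 0.12). A TAATTA 4 bp before CAGATG gives both. In windows of 1000 bp 9 layouts passed Fisher's exact test, and these were in 105 against 38 windows (adjusted p = 7.8e-07) and 130 against 31 (1.0e-13). Of the 9, 8 were more frequent in peaks, and TAATT directly before CAGATG was less frequent, in 17 against 39 windows (Fisher's exact test, adjusted p = 0.042). At spacers other than 5 bp, TAATT before CAGATG was in 17 to 57 peak windows of 1000 bp, against 130 at 5 bp. A higher frequency of the core acts on all spacers alike, so this gap argues against it as the whole cause for that layout. In windows of 400 bp the gap was small, 26 against at most 20, and spacers were not tested against each other. With peaks of a −log10 q of at least 5, TAATT at 5 bp passed Fisher's exact test, in 22 against 3 windows (adjusted p = 0.013). From the best-ranked peaks of replicate 2 alone it was in 34 against 6 windows (Fisher's exact test, adjusted p = 0.00035), and from those of replicate 1 alone in 31 against 6 (0.0035). It did not pass in peaks overlapped in both replicate lists (24 against 6; Fisher's exact test, adjusted p = 0.12). AATTA at 4 bp passed from replicate 2 alone (34 against 6; Fisher's exact test, adjusted p = 0.00035). It did not pass from replicate 1 alone (28 against 14, 0.88), at the −log10 q of at least 5 (25 against 7, 0.088) or in peaks overlapped in both lists (25 against 9, 0.38), by Fisher's exact test. With CAGCTG in place of CAGATG, TAATT at 5 bp passed as well, in 34 against 9 windows (Fisher's exact test, adjusted p = 0.0040), and AATTA at 4 bp did not (30 against 17, 0.28). The E-boxes were not compared with each other.

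Peaks found in 1 replicate could show tissue taken along in a single dissection. Among the 30000 peaks of lowest p, 578 of replicate 1 and 749 of replicate 2 had no overlap in the other replicate. Of 36 tests of nearest genes, 0 passed by Fisher's exact test after adjustment and 2 had an unadjusted p under 0.05. In replicate 1, 10 of the 578 peaks were nearest to facial mesenchyme transcription factor genes, against 189 of 29422 shared peaks (Fisher's exact test, p = 0.0055, adjusted p = 0.20), and 2 were nearest to erythroid and haematopoietic genes, against 15 (p = 0.042, adjusted p = 0.64).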

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

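The tests of this part, a count alone, were set before the data were examined. On contigs without a chromosome position there were 7 replicated peaks, above the 3 that a count of 0 allows. The report used them only in the totals per list and in the comparison of the pooled and replicated lists. The replicate lists had 6 and 9 peaks there and the pooled list 9. With 1 group of 2 samples, there was no group in which to look for a sample far from the others, and no second group to compare.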

How the results depend on the processing

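The alternatives were set before the data were examined, except the use of replicated peaks overlapped in both replicate lists, which was chosen after seeing the data. No paired analysis was possible because there was 1 group. Read depth, which limits weak peaks first, is unknown here. The cause of the changes below was not tested, except where a change of overlap, window or peak number is itself the cause.

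The number of lists and words that passed stayed within 1.5 times the reported number under every alternative: 10 to 13 lists for promoters, 4 to 6 for distal peaks and 16 to 21 words. Single lists lost 12 promoter calls and 5 distal ones, given in the report. Among words 5 calls were lost and 6 gained on the same side of 1. The gained ones were CAGATG (1.1), AP-1 (1.06) and GLI (1.71) beside the peak, CAGATG (1.01) and HNF4 (0.904) in 1000 bp, and NFI (2.0) without replicate 2. The facial mesenchyme call held in all alternatives for promoters and for distal peaks. The 15000 best-ranked peaks gave no test of replicate-only peaks, as all were overlapped in the other replicate.

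Overlap of replicate 1 and of replicate 2 was 54.2% and 44.2% where at least 50% of the peak had to be shared, 80.3% and 69.7% for peaks of a −log10 q of at least 5 in both, and 81.4% and 78.9% between the 30000 best-ranked peaks. Of the 30000 best of replicate 1, 98.1% were overlapped, and 97.8% when ranked by fold enrichment. Pooled peaks overlapped in both replicates fell from 39.1% to 28% where all peaks of each replicate together had to cover 50% of the pooled peak, and to 22.7% where a single peak of each had to. The promoter share of 20.6% became 24.6% within 2.5 kb, 21.8% (21.8033 and 21.8058) without either replicate, 26.0% at the −log10 q of at least 5 and 23.0% for peaks overlapped in both replicate lists. Joining peaks within 5 kb put 1 facial-list gene, Snai1, in the top 20 domains. Spacings that passed numbered 1 to 2 without a replicate, 1 at the −log10 q of at least 5, 9 in 1000 bp and 6 with CAGCTG, against 0.

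Some values crossed to the other side of the background or of 1. For promoters these were Hox genes of groups 1 to 4 without replicate 1 (66.7%, and 50% without replicate 2) and with pooled peaks (75%), and cardiac genes with pooled peaks (73.3%), none passing. For distal peaks the neural list had ratios of 1.18 without replicate 2 (0.941 without replicate 1), 1.05 at the −log10 q of at least 5, 1.01 within 500 kb and 1.15 by width, and Hox groups 1 to 4 had 1.09 without replicate 1 (0.898 without replicate 2), none passing.

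Among words, controls 5 kb beside the peak, of lower GC content, turned TAATTA (0.586), MEF2 (0.733), POU (0.661), RUNX (0.908) and TCF and LEF (0.850) below 1, and AGGTCA (1.07), MEIS (1.12) and REST (1.24) above it, all passing. GTAAACA had 0.999 and did not pass. Of words that had not passed, GGATTA (0.655), GATA (0.795) and CTCF (1.61) passed on the other side there, as GATA did without replicate 1 (0.940, and 1.00 without replicate 2) and CREB (1.16) and CTCF (1.57) did in 1000 bp. The rest crossed 1 without passing: beside the peak CREB (1.13) and NFI (0.895), in 1000 bp GATA (0.975) and AP-1 (0.990), at the summit CAGATG (0.985), NFI (0.906) and CTCF (1.17), in peaks overlapped in both replicate lists CREB (1.2) and CTCF (1.12), and at the −log10 q of at least 5 GATA (0.980), CREB (1.06), AP-1 (0.985), GLI (0.975), NFI (0.75) and CTCF (1.21). Without replicate 1 or 2, CAGATG had 0.994 and 0.993 and GGATTA 0.991 and 1.00, CTCF had 0.959 and 1.13, and NFI, in few windows, 0.75 without replicate 1 and 2.0 without replicate 2, the latter passing.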

Other observations

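The genes named for peak width and the Hox genes, the comparison of TAATTA with its mirror image, its counts in subsets matched again and the matching of promoter widths on fold enrichment were chosen after the values were seen. Among all marked genes, whose widest promoter peaks had a median of 1634 bp, the widest was a single peak of 22576 bp over the promoters of Skida1, Mllt10 and A930004D18Rik. It was followed by the peaks of Tbx2 with 21058 bp, Nr2f2 with 18733 bp, Cpa2 with 16173 bp, Tnrc18 with 15836 bp and Nr2f1 with 14689 bp. Further transcription factor genes with broad peaks were Meis2 with 13695 bp, the retinoic acid receptor gene Rara with 12035 bp, Id3 with 11997 bp, which encodes an inhibitor of bHLH factors, and Tbx3 with 10988 bp. The Wnt receptor gene Fzd2 had 11028 bp, and of the histone gene cluster Hist1h1d had 9505 bp. Twist1, a bHLH gene of the neural crest, had 8511 bp, and Pdgfra, the receptor gene of facial mesenchyme, 9583 bp. Of the lists, mandibular arch genes had a median of 3489 bp, housekeeping genes 2947 bp, neural and placodal genes 2210 bp, endothelial genes 1217 bp and surface ectoderm genes 1186 bp.

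Within the Hox clusters the marked members of groups 1 to 4 had unequal peaks. The fold enrichment was 10.5 at Hoxb2, 8.02 at Hoxa2 and 5.75 at Hoxa1, and 3.51 or less at Hoxb3, Hoxd3, Hoxd1 and Hoxb1. Hoxa3, Hoxa4, Hoxb4, Hoxc4 and Hoxd4 had no replicated promoter peak.

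Chromosome X had 5.51 replicated peaks per Mb and the autosomes 32.0, and the gap was wider for distal peaks (0.103 of the autosomal density, interval 0.0936 to 0.113) than for promoter peaks (0.441, 0.403 to 0.482). Masked repeats, a stand-in for sequence that reads cannot be placed on, did not account for all of it. The density per base outside them was 0.219 of the autosomal one (0.205 to 0.233). A lower share of marked genes (46.0% of X genes against 66.5%) may account for a part but not for all. Distal peaks per marked gene were 0.225 of the autosomal value (0.205 to 0.248), though a loss of weak peaks would lower that value too. A lower read dose on X, which pooled male and female embryos would have, may lose weak peaks at the caller's threshold: the density was still 0.297 of the autosomal one (0.258 to 0.341) among the 10000 peaks of lowest p, but a lower dose also moves X peaks down that ranking, so the test does not decide, and the peak lists hold no read depth per chromosome. Marked promoters had a median fold enrichment of 8.68 on X and 12.9 on the autosomes. That does not decide either, since how the background of the fold enrichment was made is unknown here. No biological explanation was tested, as there was 1 group.

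TAATTA was more frequent in distal peak windows than in matched controls, but less frequent than in windows 5 kb beside the peak, which have a lower GC content (ratio 0.586; Fisher's exact test, adjusted p = 3.9e-120). The enrichment thus holds against the matched controls and not against these neighbouring windows. The 2 comparisons differed in GC content, repeat matching, position and number of windows (59748 and 41833), so the cause of the reversal was not tested. The number of A and T bases alone did not account for the enrichment over matched controls. TAATTA was enriched 1.23 times as much as its mirror image of the same bases, ATTAAT (interval 1.14 to 1.32). That is a single word with another order of bases, and it also holds the runs TAAT and ATTA. Other features of AT-rich sequence, such as which bases lie side by side, were therefore not tested. Copies inside repeats did not account for it either, as the ratio was 1.55 in windows without a masked base (1.39 to 1.73), a subset no longer matched one to one. Matched again on chromosome and GC content, 12570 pairs of such windows gave 1.54 (1.37 to 1.73). In windows near no facial-list gene the enrichment was present, with a ratio to all controls of 1.39 (1.33 to 1.46). The ratio to these windows' own matched controls was also 1.39 (1.33 to 1.46). They numbered 58775, and 973 windows lay near a facial-list gene, so leaving the latter out could hardly move the ratio. Near a facial-list gene the matched ratio was 1.16 (0.782 to 1.72). Binding of homeodomain proteins may underlie the enrichment over matched controls, a hypothesis left untested, as their binding was not measured. The reversal beside the peak speaks neither for that hypothesis nor, given the GC content there, clearly against it.

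Promoter peaks of facial mesenchyme transcription factor genes were wide, with a median of 5702 bp. Stronger signal did not account for that, as the median was 3.15 times that of random lists of marked genes with the same fold enrichment (mean 1813 bp, range of 95% of lists 1559 to 2109 bp). CpG content within 1 kb of the TSS did not either, at 3.19 times lists matched on it (1790 bp, 1478 to 2128 bp). That count covers less sequence than these peaks, so CpG-rich sequence further out was not tested. Broad acetylation at genes that set cell identity is a hypothesis that these values leave open, and no biological explanation was tested, as there was 1 group.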
